A study of Glycine max with 11 samples.

How the data were processed

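RNA of soybean stems was hybridised to Affymetrix arrays, 1 array per sample, in 4 groups: stage 1 controls (n = 2), stage 1 parasitized stems (n = 3), stage 2 controls (n = 3) and stage 2 parasitized stems (n = 3). Per the labels' protocols, plants grew at 30 °C with 12 h of light, biotin-labelled RNA was made from 100 ng of total RNA, and Cuscuta and the soybean stem were excised and collected; whether they were separated before extraction is not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The titles call the samples biological replicates, but do not say how many plants each held.

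The deposited values are log2 expression values that the authors made with RMA in Affymetrix Power Tools, per the submitters' processing notes. The software version, the settings and the genome build are not given in the sources used here, and the base of the logarithm was taken from the range of the values. RMA subtracts background, gives the arrays a near-common distribution and summarises probes, so a change shared by most transcripts would be removed, and changes of dim features are compressed. No scanner files, detection calls or scan dates were used here, so no background limit or batch could be tested. Every per-sample column of the table was used.

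The table held 66659 features without missing values. The 66555 with 8-digit IDs were tested, a range that holds every feature with a gene name, and the 104 with 6-digit IDs, whose kind is not known here, were kept out. The design fixed before the data were examined had assumed an older array with probe sets of other organisms and labelled control probe sets. The checks of cross-hybridization and of array controls that relied on them could not be run, and all 8-digit features took the place of the soybean probe sets. In all, 272 features shared all their values with another feature, 157 of them surplus, and were counted as features.

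Gene names came from the platform's annotation of 2015, in which 3085 features had 1 gene, 54 had several and were given no name, and the other 63416 tested features had none. Of the 3085, 3072 were found by gene identifier in the reference gene table of assembly Glycine_max_v4.0. Where a gene had several features, the brightest on average was used. Of 718 genes with a descriptive symbol, 49 had several features. No coordinates are given, because the build of the array is not given in the sources used here.

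A model with a mean per group was fitted over all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 7 residual and 4.65 prior degrees of freedom), so that the stage 1 controls shared the spread of the other groups. These contrasts were tested, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05 without a fold minimum: parasitized against control at each stage, the difference between these effects, and stage 2 against stage 1 controls. Errors given with log2 changes are standard errors from this model, and those given with group levels are SDs. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, 1 feature per gene, for lists of 5 genes or more. Camera compared each list with all other genes and with the tested features without a gene name, which made up most of this background. Benjamini-Hochberg adjustment was over lists within a contrast, separately for the 2 sets of lists.

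Before the data were examined, 25 lists were fixed as patterns on gene names. Because the gene tables held symbols and synonyms but no descriptions, 7 lists had 5 genes or more, 9 had 1 to 4 and 9 had none. A further 17 lists were written after the symbols were seen and before any test. The rule for named genes, also fixed before, took the 6 largest rises and falls per stage among named genes past the threshold with no overlap of arrays, the 2 members of each list with the largest change past the threshold, and the 4 highest and lowest genes of the other contrasts. Where fewer than 4 features passed, the 4 named genes per direction with the lowest p were given as values.

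The fit was tested on simulated arrays with known changes over 66555 features. For the stage 1 comparison it recovered 62 of 100 features changed by a log2 value of 1 and 99 of 100 changed by 2, with 9 false calls. For stage 2 it recovered 72 and 100, with 5 false calls. Alternatives changed the eBayes prior, the array normalization, array weights, the features tested, the fold minimum, the samples fitted, the replicate number as a block and each array left out. An intensity filter was added after seeing the data.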

Results

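Gene expression was measured on Affymetrix arrays in soybean (Glycine max, cultivar given as William 82) stems with and without Cuscuta, the dodders, leafless parasitic plants that wind around a host stem and draw water and nutrients from it through haustoria. Cuscuta seedlings 7 days old were fixed to the epicotyl of 9-day-old soybean plants, and material was collected 1.5 days (stage 1) and 1 week (stage 2) after attachment. Stage 1 held 2 control and 3 parasitized arrays, and stage 2 held 3 of each, all named as biological replicates in the labels. The array reports 66555 features that were tested, of which 3085 are paired with 1 gene. Named genes are here the 718 genes with a descriptive symbol, so most changes below fall in features that have no gene name here. Array medians lay between 4.62 and 4.68 on the log2 scale, and the number of arrays limits the precision of every value.

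Replicate arrays correlated with r between 0.974 and 0.991 across features. The first principal component, with 47.5% of the variance, placed the stage 2 parasitized stems (107.4 to 119.1) apart from the stage 2 controls (-12.25 to 1.826) and from all stage 1 arrays (-72.07 to -58.03). On the second component, with 26.1%, the stage 2 controls (-95.93 to -87.38) stood apart, while the stage 2 parasitized stems (28.34 to 31.85) lay within the range of the stage 1 arrays (27.85 to 41.06). Stage 2 control replicate 2 stood furthest from its group on the third component (78.02 against -41.88 and -31.78) and had the lowest array weight, 0.406.

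**Figure D1:**
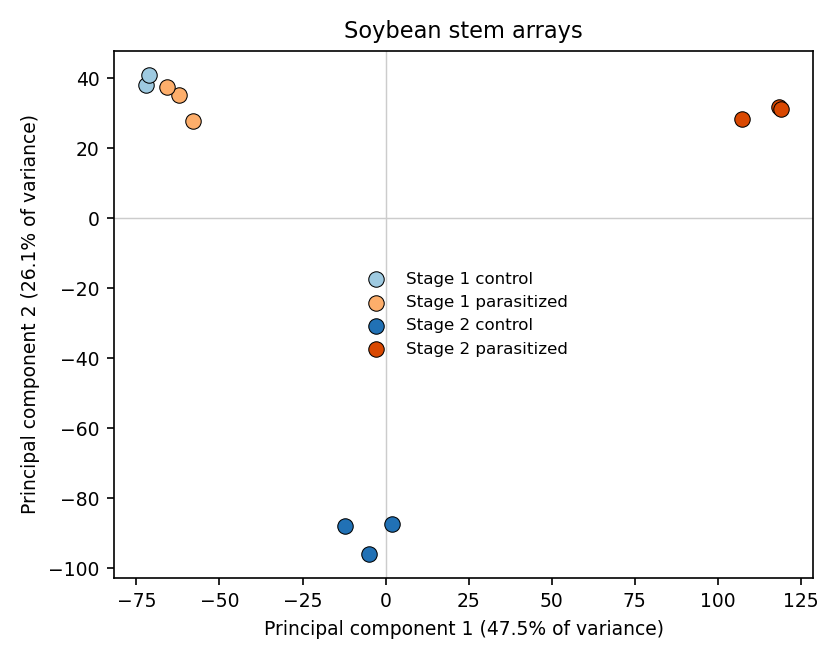
Principal components 1 and 2 of the 11 arrays over 66555 features (axes in component scores on the log2 scale), each point 1 array, coloured by group. The 3 stage 2 parasitized arrays lie between 107.4 and 119.1 on component 1, and the 3 stage 2 controls lie below -87 on component 2, where all other arrays lie above 27.

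The comparison at stage 1 asks which soybean transcripts differed within 1.5 days of attachment. Only 2 features passed, both higher in parasitized stems and neither with a gene name. Feature 12022047 rose from 3.48 to 5.36 (log2 change 1.88 ± 0.21 SE, adjusted p = 0.0405) and feature 12059267 rose from 6.98 to 8.29 (log2 change 1.32 ± 0.13, adjusted p = 0.039; n = 2 and 3). Both were also higher in stage 2 parasitized stems, at 6.28 against 3.84 and 10.16 against 6.99. No named gene passed at stage 1. Among named genes, the lowest unadjusted p-values of positive changes belonged to the isoflavone synthase IFS2 (log2 change 0.73 ± 0.17), the proline-rich protein gene PRP (1.09 ± 0.28), SLTI114 (0.57 ± 0.14) and the fatty acid desaturase FAD2-1 (0.66 ± 0.22), with adjusted p between 0.47 and 0.57. Those of negative changes belonged to AMS1 (-1.45 ± 0.26), the lipoxygenase LOX10 (-1.13 ± 0.27), MYB114 (-0.68 ± 0.17) and the early light-induced protein gene ELIP (-1.58 ± 0.42), with adjusted p between 0.38 and 0.54.

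No gene list passed at stage 1 by limma's camera test. The 57 WRKY genes had a median log2 change of 0.06 (adjusted p = 0.36), the 30 glutathione S-transferase genes -0.04 (0.36), the 11 phenylpropanoid and isoflavonoid genes -0.02 (0.958), the 11 jasmonate genes -0.04 (0.36), the 14 gibberellin-related genes -0.05 (0.958), the 5 heat shock genes 0.18 (0.36) and the 6 water and nitrate transport genes -0.11 (0.36). Adjusted over the list alone, IFS2 passed among the phenylpropanoid genes and LOX10 among the jasmonate genes. In lists written after the symbols were seen, IFS2, LOX10, MYB114, PRP and ELIP passed in the same way, each as the 1 such member of its list. Of these 17 lists none passed, and the lowest adjusted p was that of the 17 NAC genes (median -0.31, adjusted p = 0.0536). The NAC list passed in 5 of the 11 fits that left out 1 array, with adjusted p from 0.0129 to 0.439 over the 11, and the NAC and cell wall lists passed with all features of a gene as members (adjusted p = 0.0179 for each). The seed list passed without stage 1 parasitized replicate 3 (adjusted p = 0.0441). The median and the mean differed in sign for the gibberellin-related genes (-0.05 and 0.03), the defence genes (0.04 and -0.02), the proteinase inhibitors (0.08 and -0.10) and the peroxidases (0.03 and -0.06). In limma, 4881 features (7.33%, where chance gives 5%) had an unadjusted p under 0.05. A test per feature with unequal variances gave 0 features, and 3787 unadjusted. The count of 2 was 0 when any stage 1 array, any stage 2 parasitized array or stage 2 control replicate 3 was left out.

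The comparison at stage 2 asks the same after 1 week, and here the stems differed widely. WRKY genes, which encode plant transcription factors many of which act in defence, held 4 of the 6 largest rises among genes with a descriptive symbol. WRKY58 rose 35.6-fold from 3.78 ± 0.28 to 8.93 ± 0.23 (SD, n = 3 each), with a log2 change of 5.15 ± 0.23 (SE). WRKY30 rose by 4.84 ± 0.13, WRKY60 by 4.52 ± 0.40 and WRKY55 by 4.29 ± 0.26 on the same scale. B13-1-9 (4.95 ± 0.42) and SCOF-1, a cold-inducible zinc finger protein gene (4.51 ± 0.32), completed the 6, and adjusted p lay between 1.2e-09 and 9.4e-06. The largest falls among genes with a descriptive symbol were those of XET1, a xyloglucan endotransglycosylase gene of the cell wall, from 12.06 ± 0.43 to 8.73 ± 0.36 (log2 change -3.33 ± 0.23), MYB114 (-2.40 ± 0.15), the gibberellin-regulated GASA7 (-2.21 ± 0.25), the CONSTANS-like COL2A (-2.13 ± 0.19), the asparaginase gene ASP1 (-2.12 ± 0.22) and the early nodulin gene ENOD40B (-2.10 ± 0.18), with adjusted p between 6.2e-07 and 6.2e-05. In these 12 genes the arrays of the 2 groups did not overlap, which was part of the rule that chose them. WRKY30 and B13-1-9 had control levels of 2.83 and 3.18, close to the lower quartile of all values (2.93).

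Of 66555 features, 15192 (22.8%) passed at stage 2, 6983 higher and 8209 lower, and 3053 of the rises and 2253 of the falls were at least 2-fold. A test per feature with unequal variances gave 1362 features, 55.8% of them higher against 46% in limma. Of the 718 named genes, 172 rose and 127 fell, so named genes rose more often than features as a whole. The camera tests below set each list mostly against features without a gene name. A list can therefore stand above that background without standing above other named genes. Only the WRKY list was also compared with other named genes. The collected material included Cuscuta tissue according to the labels, and the share of Cuscuta RNA in each sample was not measured.

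Of the 57 WRKY genes measured, 37 rose, 5 fell and 15 did not pass (39 and 9 adjusted over the list alone). The median log2 change was 1.32, and the list stood above the other features by camera (adjusted p = 2.21e-19), which held with an estimated correlation (adjusted p = 0.0207). The 5 that fell, named after their values were seen, were WRKY10 (-1.96), WRKY45 (-0.99), WRKY22 (-0.60), WRKY35 (-0.55) and WRKY41 (-0.39). The 57 include LOC100170685, which has no descriptive symbol. Among the 662 named genes outside the list 136 rose (20.5% against 64.9%; odds ratio 7.13, confidence interval 3.89 to 13.4, two-sided Fisher's exact test p = 7.89e-12), a comparison added after the data were seen in which genes of a family count as independent.

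Glutathione S-transferases, which conjugate glutathione to reactive compounds, formed the other list that held with an estimated correlation. Of 30 genes 13 rose and 3 fell (15 and 3 adjusted over the list alone), with a median log2 change of 0.38 (camera adjusted p = 2.86e-05, and adjusted p = 0.0265 with an estimated correlation). The tau-class gene with the synonym GSTU21 rose from 4.07 ± 0.77 to 8.63 ± 0.17 (log2 change 4.56 ± 0.30). GSTU42 rose by 3.20 ± 0.14 from 2.99, a level close to the lower quartile of all values (2.93). The 3 falls, named after their values were seen, were those of GSTU37 (-1.48), LOC547576 (-0.91) and GSTT1 (-0.77).

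Of 11 phenylpropanoid and isoflavonoid genes 6 rose and 1 fell, and the counts were the same adjusted over the list alone. The camera adjusted p was 2.86e-05, and the call was lost with adjusted p = 0.112 with an estimated correlation. IFS2, the isoflavone synthase that opens the isoflavonoid branch, rose from 7.21 ± 0.06 to 10.27 ± 0.32 (log2 change 3.06 ± 0.15), and the chalcone synthase gene CHS8 rose from 3.93 ± 0.61 to 6.50 ± 0.25 (2.57 ± 0.27). The fall was in the phenylalanine ammonia-lyase gene PAL2.1 (-0.38), named after its value was seen. In a wider list of 27 isoflavonoid and flavonoid enzymes, written after the gene symbols were seen and sharing members with the first, 10 rose and 4 fell (camera adjusted p = 0.00719, and adjusted p = 0.375 with an estimated correlation). There G4DT, which encodes a prenyltransferase of glyceollin synthesis, rose by 2.65 ± 0.38 from 2.72, a level below the lower quartile of all values.

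**Figure D2:**
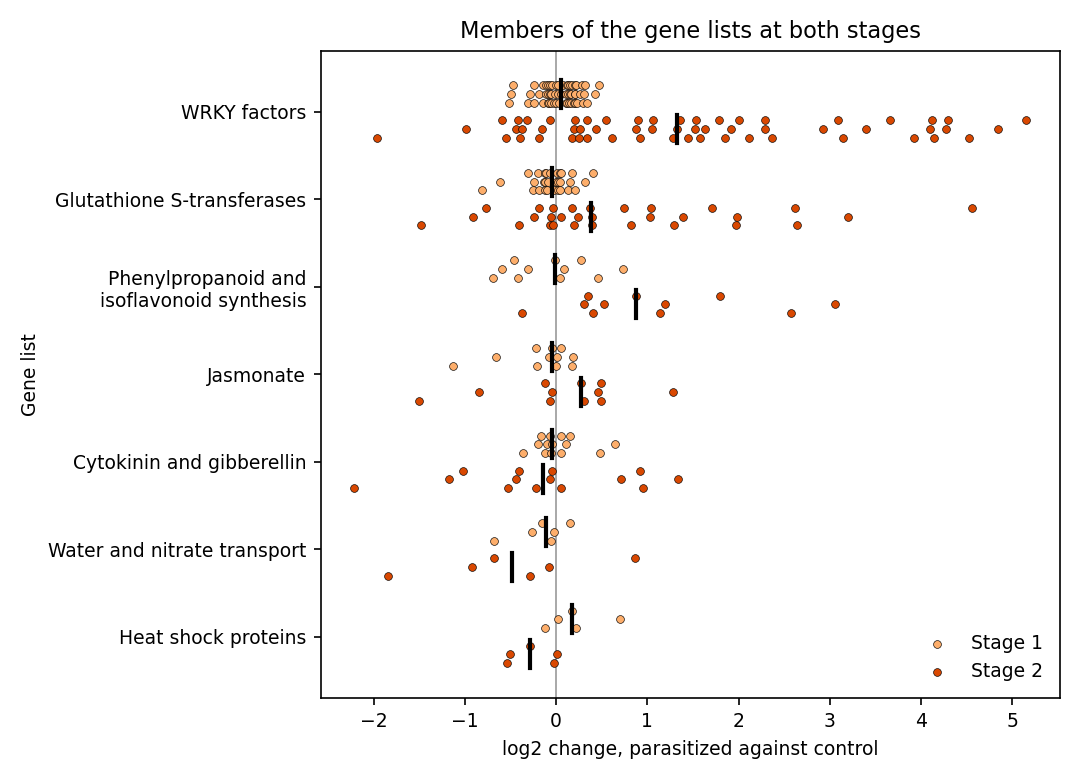
log2 change of parasitized against control stems (horizontal axis) for every measured member of 7 gene lists (vertical axis), with stage 1 in pale and stage 2 in dark orange, each point 1 gene and each black bar the list's median. The WRKY median is 0.06 at stage 1 and 1.32 at stage 2, and the glutathione S-transferase medians are -0.04 and 0.38.

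The other fixed lists did not pass at stage 2. Jasmonate genes split, with 2 of 11 higher and 2 lower (camera adjusted p = 0.485). The lipoxygenase gene LOX10 rose by 1.28 ± 0.25 on the log2 scale, and the vegetative storage protein gene VSPA fell from 11.41 ± 0.91 to 9.91 ± 0.28 (SD, adjusted p = 0.0074). All 14 members of the cytokinin and gibberellin list were GASA genes, of which 3 rose, GASA3 the most (1.34 ± 0.24), and GASA7 fell (adjusted p = 0.822). None of the 5 heat shock genes passed (adjusted p = 0.485). Among 6 water and nitrate transport genes (adjusted p = 0.177), the tonoplast aquaporin gene with the synonym TIP2-3 fell by 1.85 ± 0.15 and the nitrate transporter gene NRT1-1 fell by 0.92 ± 0.14, while PIP2-1, named after its value was seen, rose by 0.87. Counts adjusted over each of these lists alone were the same. In lists with 1 to 4 genes, which were not tested as lists, CYSTATIN (0.68 ± 0.13), the proliferating cell nuclear antigen gene with the synonym PCNA (1.29 ± 0.14) and ENOD93 (1.55 ± 0.28) rose, and the chlorophyll-binding protein gene CAB3 (-0.86 ± 0.11), the auxin efflux carrier gene PIN1C (-0.71 ± 0.15) and the sugar transporter gene SWEET34 (-1.15 ± 0.13) fell. In the list of 4 root and nodule genes that holds ENOD93, ENOD40B (-2.10) and ENOD55-1 (-0.48) fell, the last named after its value was seen. The pathogenesis-related genes PR1-1 (2.62 in stage 2 controls, log2 change 0.05) and PR-10 (1.83, log2 change 0.71) did not pass, with levels in controls below the lower quartile of all values. PR-10 passed adjusted over its list alone.

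Lists written after the gene symbols were seen, and before any test, added further groups, none of which held with an estimated correlation. Such a loss need not mean that the members were correlated. The estimated correlation was -0.00137 for the bZIP genes and -0.0495 for the proteinase inhibitors, below the preset 0.01. Their unadjusted camera p still rose, from 0.00389 to 0.0184 and from 0.00886 to 0.0309. Of 24 defence genes 9 rose and 2 fell (camera adjusted p = 0.00116, and adjusted p = 0.157 with an estimated correlation), among them NDR1b (2.41 ± 0.20) and HS1pro1 (2.41 ± 0.38). Of 7 proteinase inhibitor genes 4 rose and none fell (0.0333, and adjusted p = 0.175 with an estimated correlation), with the Kunitz trypsin inhibitor genes KTI-3 at 2.66 ± 0.29 and KTI-2 at 1.40 ± 0.27. Of 13 bZIP transcription factor genes 7 fell and 2 rose (0.022, and adjusted p = 0.157 with an estimated correlation), with BZIP36 at -2.01 ± 0.15 and BZIP59 at 1.28 ± 0.15. Of 13 WNK kinase genes 6 fell and none rose (0.0333, and adjusted p = 0.23 with an estimated correlation), with WNK12 at -1.66 ± 0.14 and WNK10 at -1.18 ± 0.13. With the intensity filter, chosen after seeing the data, the bZIP and WNK calls were lost (adjusted p = 0.0832 and 0.147).

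Of 11 antioxidant enzyme genes 5 fell and none rose (camera adjusted p = 0.0473, and adjusted p = 0.193 with an estimated correlation), with the catalase gene CAT5 at -1.97 ± 0.14 and the iron superoxide dismutase gene SODB at -1.89 ± 0.44. Of 9 chlorophyll and photosynthesis genes 4 fell and none rose (0.0473, and adjusted p = 0.375 with an estimated correlation), among them CHLH, a magnesium chelatase subunit gene (-1.29 ± 0.14), and PETC (-1.22 ± 0.16). Of 13 fatty acid desaturase genes 5 rose and 1 fell (0.0473, and adjusted p = 0.193 with an estimated correlation), with FAD7-1 at 2.57 ± 0.34 and FAD6.1 at -1.61 ± 0.13. These 3 calls were lost in 7, 4 and 4 of the 11 fits that left out 1 array, with adjusted p up to 0.0831, 0.135 and 0.07, and all 3 were lost with the intensity filter (adjusted p = 0.147 for each). The antioxidant and chlorophyll calls were also lost after quantile normalization again (adjusted p = 0.0749 and 0.093) and after median centring (0.0573 and 0.0537). With the replicate number as a block the chlorophyll call was lost too (0.0581).

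Other lists of this kind did not pass at stage 2. Of 14 cell wall genes 7 rose and 3 fell (camera adjusted p = 0.134). CIM1, a cytokinin-induced expansin gene, rose from 5.08 ± 0.39 to 9.30 ± 0.65 (log2 change 4.22 ± 0.32). Of 13 ethylene and DREB/ERF genes 5 rose and 2 fell (0.0959), with the ethylene synthesis gene ACS at 2.01 ± 0.15 and ERF6 at 2.02 ± 0.22. This list passed with all features of a gene as members (adjusted p = 0.0208) and without stage 2 parasitized replicate 3 (0.0425). Of 17 NAC transcription factor genes 3 rose and 4 fell (0.797), with NAC6 at 2.58 ± 0.23 and NAC35 at -1.67 ± 0.18. Of 11 MYB genes 2 rose and 2 fell (0.797), with MYB128 at 1.46 ± 0.19. Of 7 auxin genes 1 rose and 2 fell (0.588), with ADR11 at 2.47 ± 0.16 and AUX22 at -1.27 ± 0.27. AUX22 stood at 3.05 in stage 2 controls, close to the lower quartile of all values (2.93), and at 1.77 in stage 2 parasitized stems, below it. Of 5 peroxidase genes 2 rose and 2 fell (0.359), with the seed coat peroxidase gene Ep at 2.03 ± 0.27 and PRX4 at 1.75 ± 0.14. Of 9 sugar transport and sucrose genes 1 rose and 1 fell (0.797), with MST1 at 0.75 ± 0.16. Lists meant as markers of tissues outside the stem gave 0 rises and 5 falls among 37 seed genes (0.0897) and 1 rise and 3 falls among 14 nodulin genes (0.359). Among the seed genes PM37 changed by -1.03 ± 0.18 and PM23 by -1.02 ± 0.13, and among the nodulin genes N-36A by -1.97 ± 0.13. In stage 2 controls PM37, PM23 and N-36A stood at 7.30, 9.19 and 8.81. These levels lie above the median of all values (4.66). Whether the signal came from the stem or from other tissue collected with it cannot be told from levels alone. These genes therefore do not decide the tissue content of the samples. The median and the mean differed in sign for the MYB genes (0.01 and -0.06) and the sugar genes (0.22 and -0.04).

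**Figure D3:**
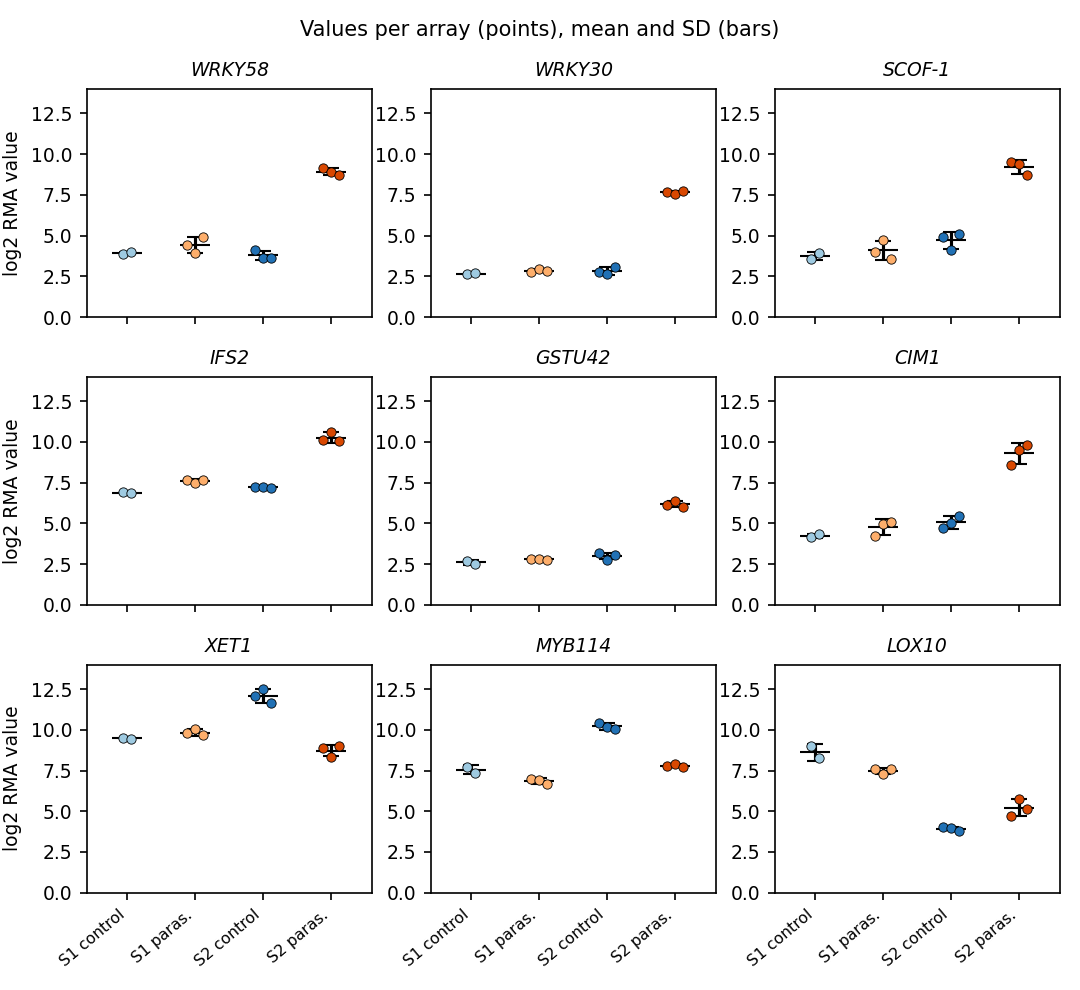
log2 values per array (vertical axis, log2 RMA value) of 9 named genes in the 4 groups (horizontal axis; S1 and S2 are stages 1 and 2, paras. is parasitized), with each point 1 array and bars the mean and SD (n = 2 for stage 1 control, 3 otherwise). WRKY58 averages 8.93 in stage 2 parasitized stems and 3.78 in stage 2 controls, while XET1 averages 12.06 in stage 2 controls and at most 9.83 elsewhere.

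The difference of the parasitization effect between the stages was tested directly. The effect on WRKY60 was higher at stage 2 than at stage 1 by 5.04 ± 0.61 on the log2 scale, on WRKY58 by 4.68 ± 0.34, on WRKY30 by 4.65 ± 0.20 and on B13-1-9 by 4.64 ± 0.63. It was lower for XET1 (-3.69 ± 0.34), GASA7 (-2.37 ± 0.38), BZIP36 (-2.10 ± 0.22) and ASP1 (-2.10 ± 0.33), and adjusted p of the 8 genes lay between 1.9e-07 and 0.0018. In the WRKY list 34 of 57 genes had a higher effect at stage 2 and 2 a lower one, and 37 and 5 adjusted over the list alone (camera adjusted p = 1.23e-18, and adjusted p = 0.0151 with an estimated correlation). In the glutathione S-transferase list 11 of 30 were higher and 3 lower, and 13 and 3 adjusted over the list alone (camera adjusted p = 3.58e-06, and adjusted p = 0.0151 with an estimated correlation). Of the 11 phenylpropanoid and isoflavonoid genes 6 were higher and none lower, and 6 and 1 adjusted over the list alone (1.79e-05, and adjusted p = 0.111 with an estimated correlation). The jasmonate (adjusted p = 0.305), gibberellin-related (0.766), heat shock (0.305) and water and nitrate transport genes (0.305) did not pass. Among lists written after the symbols were seen, the effect on the isoflavonoid and flavonoid enzymes was higher in 10 and lower in 1 of 27 genes (0.00192, and adjusted p = 0.38 with an estimated correlation). It was higher in 6 and lower in 1 of 24 defence genes (0.00192, and adjusted p = 0.135 with an estimated correlation), and higher in 2 and lower in 7 of 13 bZIP genes (0.00949, and adjusted p = 0.135 with an estimated correlation). It was lower in 3 of 37 seed genes (0.0279, and adjusted p = 0.38 with an estimated correlation), a call lost in 3 of 11 fits that left out 1 array and after quantile normalization again (adjusted p = 0.0509). The proteinase inhibitors (adjusted p = 0.0725) and the fatty acid desaturases (0.077) did not pass, but passed without stage 2 parasitized replicate 1 (0.0489) and replicate 3 (0.0474), respectively, and the proteinase inhibitors also passed with the intensity filter (0.0243).

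Over all features 7838 passed this test, 4169 with a higher and 3669 with a lower effect at stage 2. The count was 4884 without stage 1 control replicate 1 and 4357 without stage 1 control replicate 2. Across features, the effects of the 2 stages, which share no arrays, correlated with Pearson r = 0.0427 and Spearman rho = 0.0343. The Pearson value was 0.0194 without stage 1 control replicate 1, 0.0111 without stage 2 control replicate 2 and 0.0695 without stage 2 parasitized replicate 2. Features are not independent replicates. Among features that passed at stage 2, 52.8% had the same direction at stage 1, against 50.0% of the others, a comparison added after the data were seen. The stage 1 effect in the stage 2 direction had a median of 0.02 in these features, where the median size at stage 2 was 0.81. The 2 features that passed at stage 1 also passed at stage 2, in the same direction, where independent lists would share 0.21.

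The controls of the 2 stages were compared to show what differed between unparasitized stems of the earlier and the later collection. Among genes with a descriptive symbol SODB, which encodes an iron superoxide dismutase, rose the most, from 2.88 to 8.59 (log2 change 5.71 ± 0.50; n = 2 and 3), followed by SODB2 (4.77 ± 0.24), INR1 (3.51 ± 0.44) and BZIP36 (3.31 ± 0.16). Among genes with a descriptive symbol the largest falls were those of the lipoxygenase genes LOX10 (8.63 to 3.93, log2 change -4.70 ± 0.27) and LOX7 (-4.69 ± 0.32) and of the flavonoid genes F3H (-4.63 ± 0.52) and W1 (-4.54 ± 0.31). Adjusted p of the 8 genes lay between 8.6e-07 and 2.4e-04. SODB and SODB2 stood at 2.88 and 2.90 in stage 1 controls, below the lower quartile of all values (2.93). The sizes of their rises thus rest on levels not shown to be above background. Of 11 jasmonate genes 7 fell and none rose, with the same counts adjusted over the list alone (median -1.34, camera adjusted p = 2.33e-05, and adjusted p = 0.0672 with an estimated correlation).

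Of 57 WRKY genes 14 rose and 3 fell, with the same counts adjusted over the list alone (0.0124, and adjusted p = 0.441 with an estimated correlation). The WRKY call was lost without stage 2 control replicate 1 (adjusted p = 0.102). The phenylpropanoid (adjusted p = 0.538), glutathione S-transferase (0.275), gibberellin-related (0.194), heat shock (0.528) and water and nitrate transport genes (0.335) did not pass. Among lists written after the symbols were seen, 7 of 17 NAC genes rose and none fell (0.00107, and adjusted p = 0.263 with an estimated correlation). In the ethylene and DREB/ERF list 7 of 13 genes rose and none fell (8.63e-04, and adjusted p = 0.143 with an estimated correlation), and in the bZIP list 6 rose and 2 fell (0.0126, and adjusted p = 0.143 with an estimated correlation), a call lost with the intensity filter (adjusted p = 0.0598). The seed (adjusted p = 0.0882) and WNK lists (0.0624) did not pass, but passed without stage 1 control replicate 1 (0.0367 and 0.0331) and without stage 2 control replicate 2 (0.0395 for each), and the sugar list (0.107) passed with all features of a gene as members (0.0322). The median and the mean differed in sign for the isoflavonoid and flavonoid enzymes (0.12 and -0.30), the defence genes (0.20 and -0.23), the proteinase inhibitors (0.10 and -0.76) and the antioxidant enzymes (-0.04 and 0.89), none of which passed.

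Over all features 13285 differed between the control stages, 6405 higher and 6880 lower at stage 2. The count was 7716 without stage 1 control replicate 1, 7246 without stage 1 control replicate 2, and 8265 when only the control arrays were fitted.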

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

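Of the tests reported here, those of the spread between arrays and of dilution by Cuscuta RNA were chosen only after the results they concern had been seen, and binding of Cuscuta RNA to probes, raised at the same time, was not tested.

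Results were singled out here because the effect of parasitization differed between the stages by the test of the difference itself, and values are stage 2 effects minus stage 1 effects on the log2 scale. Over all features 7838 passed, and of the 718 named genes 121 had a higher and 73 a lower effect at stage 2. The genes below are only part of these. They are those that the rule for named genes had chosen, mostly by their stage 2 change, and FKF1 from a list of day-time genes. The transcription factor genes were WRKY58 (4.68), WRKY30 (4.65), WRKY60 (5.04), WRKY55 (4.38), SCOF-1 (4.17), NAC6 (3.00), NAC35 (-1.53), MYB128 (1.56), MYB114 (-1.72), BZIP36 (-2.10), BZIP59 (1.07), ERF6 (1.66) and COL2A (-1.79). Genes of flavonoid and defence functions were IFS2 (2.33), CHS8 (3.26), G4DT (2.46), NDR1b (2.33), HS1pro1 (2.06), KTI-3 (3.21), KTI-2 (2.12) and LOX10 (2.41). Genes of detoxification and redox functions were LOC547581, which has the synonym GSTU21 (4.50), GSTU42 (3.02), CAT5 (-2), Ep (2.42), PRX4 (1.96) and SODB2 (-1.90). Genes of the cell wall and of hormones were XET1 (-3.69), CIM1 (3.68), PRP (-1.51), GASA7 (-2.37), GASA3 (1.39), PIN1C (-0.85), ADR11 (2.08) and ACS (1.58). Genes of photosynthesis, transport and lipids were CAB3 (-0.84), CHLH (-1.06), PETC (-1.01), SWEET34 (-0.81), LOC100306092, which has the synonym TIP2-3 (-1.59), NRT1-1 (-0.86), FAD7-1 (2.43) and FAD6.1 (-1.45). The remaining genes were B13-1-9 (4.64), ASP1 (-2.10), ENOD40B (-1.91), ENOD93 (1.48), N-36A (-2.10), PM23 (-1.01), LOC548079, which has the synonym PCNA (1.5), WNK12 (-1.78), WNK10 (-0.96), AMS1 (2.92) and FKF1 (0.89). Mean differences of lists were 1.47 for the WRKY genes, 0.817 for the glutathione S-transferases and 1.16 for the phenylpropanoid and isoflavonoid genes. In lists written after the symbols were seen they were 0.696 for the isoflavonoid and flavonoid enzymes, 0.644 for the defence genes, -0.62 for the bZIP genes and -0.268 for the seed genes. Of these lists, only the WRKY and glutathione S-transferase lists held with an estimated correlation.

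Many more features passed at stage 2 (15192) than at stage 1 (2). The Benjamini-Hochberg threshold loosens as more features pass. Without adjustment, 22122 features (33.2%) at stage 2 and 4881 (7.33%) at stage 1 had p under 0.05 in limma. Fewer control arrays at stage 1 would not account for the higher stage 2 count. At least 13297 features passed at stage 2 with any of its controls left out. The median SD within groups at stage 1 was 0.87 times that at stage 2, so the spread as a whole was not larger at stage 1. Among parasitized stems alone it was 0.165 at stage 1 and 0.151 at stage 2. The model pooled the spread over all groups, so this ratio cannot decide what set the stage 1 count. Dilution of soybean RNA by Cuscuta RNA stays open as a cause of falls: their quartiles lay 0.475 apart around a median of -0.75, where noise around 1 common size would give 0.207, and 15.5% exceeded the median by more than 0.5, but the calling threshold sets part of this range and RMA compresses features unequally. Cuscuta RNA that binds to soybean probes could account for some of the 3053 rises of at least 2-fold and cannot be excluded without probe or Cuscuta sequences, while a longer parasitization is the untested biological explanation that the design names. The real split of the 6 stage 2 arrays was the 1 of 10 with as many features, and the highest of the others called 1, but 10 splits are too few for a share under 0.05.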

How the results depend on the processing

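Counts are of features past the threshold. The intensity filter, on features whose highest group mean was above the median of all features, was chosen after seeing the data, and the other alternatives before the data were examined. It gave 2, 14907, 8652 and 13679 features at stage 1, at stage 2, for the difference and for the control stages. The planned filter on probe sets of other organisms and the set without probe sets shared between genes could not be run, since the features carry no such IDs. At stage 1 the count of 2 became 1 after quantile normalization again, 0 with only the stage 1 arrays, 0 in a test per feature with unequal variances and 0 to 2 with 1 array left out. At stage 2 the 15192 became 5306 with a log2 fold minimum of 1, which removes small changes by construction, and 1362 in the test with unequal variances, which does not share the spread across features. It was 11696 to 15810 with 1 array left out, and between 75 and 86.5% of the features called over all arrays remained when a stage 2 array was left out. The difference between stages became 5166 with the fold minimum and 4357 to 9919 with 1 array left out. The control stages became 5112 with the fold minimum, 8265 with the control arrays alone and 7246 to 14885 with 1 array left out. A stage 1 control left alone was assumed to vary like the other groups. The correlation of the 2 effects was 0.0111 (without stage 2 control replicate 2) to 0.0695 (without stage 2 parasitized replicate 2) with 1 array left out, 0.0194 without stage 1 control replicate 1, and stayed above 0 in every setting run. For all other changed values the cause was not tested.

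Whether the replicate numbers pair the samples could not be decided. Same-numbered arrays deviated from their group means with correlations of 0.0276 and -0.0427 at stage 1 and 0.0368, 0.062 and -0.013 at stage 2. The 2 stage 1 controls deviate by equal and opposite amounts, so the stage 1 values are not separate evidence. At stage 2, control replicates 1 and 2 correlated best with their own number, and control replicate 3 with another number (0.0563). With the number as a replicate block the counts were 0 at stage 1, 14330 at stage 2, 6605 for the difference and 11847 for the controls, and with a replicate block within stage they were 0, 13502 and 5643 for the first 3.

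Median centring gave 39.7% higher calls at stage 2 in place of 46%. Named genes kept their side of the threshold in all 1518 checks, and most had been chosen by large changes past it in these same data. These checks left out the fold minimum, the test with unequal variances and the fits of only the compared groups. Named genes with smaller changes at stage 2, such as CYSTATIN (0.68) and PIN1C (-0.71), would not pass the log2 fold minimum of 1. List tests kept their side in 1729 checks, lost a call in 50 and gained 1 in 45. No gene or list that passed in either fit changed direction, and direction was not compared where neither fit passed. Of the gains, 26 came from limma's fry, which tests a list against no change and not against other genes. The chlorophyll and photosynthesis call at stage 2 was lost with the replicate block (adjusted p = 0.0581), and the proteinase inhibitors passed with it for the difference between stages (0.0454). No background limit was used here.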

Other observations

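The tests of held-out control arrays and of the time of day were written before their results were seen, but the list of day-time genes was written after the values of MYB114 were known, and the simulation of the held-out arrays was added after their result was seen.

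Features were chosen by a log2 difference of at least 1 between the control stages on some control arrays, not by adjusted p. Their levels were then measured on the other control arrays, over 6 choices of arrays. In 64.7 to 74.3% of these features, stage 2 parasitized stems lay on the stage 1 side of the held-out stage 2 control. This side includes levels beyond that of stage 1. Simulated parasitized arrays at the stage 2 control level gave 49.5 to 50.6% in 20 simulations. Each simulated value is a mean over the 6 choices, while the observed range is over single choices, so the 2 ranges are not alike. The simulations hold no deviations shared across an array. XET1, for example, stood at 9.47 in stage 1 controls, 12.06 in stage 2 controls and 8.73 in stage 2 parasitized stems, and BZIP36 at 5.74, 9.05 and 7.04. LOX10 stood at 8.63, 3.93 and 5.21. These levels are means over all control arrays, in genes named for large changes, so they only illustrate the pattern. Other named genes lay further from stage 1 in stage 2 parasitized stems than in stage 2 controls. VSPA stood at 12.94, 11.41 and 9.91 in the same groups, and ACS at 4.30, 5.70 and 7.71. F3H hardly moved between the stage 2 groups (8.26, 3.63 and 3.79).

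The comparison of the control stages and that of stage 2 both use the stage 2 controls, and unchanged simulated groups gave a correlation of -0.447 and a covariance of -0.0179 between their log2 changes, against an observed -0.301 and -0.116. In the features chosen on some control arrays and measured on others, stage 2 parasitized stems kept 0.642 to 0.8 of the control change; noise of the shared arrays would give about 1, but the highest share did not fall below the bound of 0.8 set beforehand, so noise as part of the pattern cannot be excluded. This rests on stage 2 control replicate 2, which stood apart from its group: holding it out gave 0.785 and 0.8, and the other 4 choices gave 0.642 to 0.694. Collection at another time of day stays open. At stage 2, MYB114, which has the synonym GmLHY2b and was listed as a morning gene, fell by 2.40 on the log2 scale. The evening gene FKF1 rose by 1.13 ± 0.15, but the evening gene TOC1 gave 0.21 ± 0.12 (adjusted p = 0.24). Between the control stages MYB114 changed by 2.67 ± 0.17, FKF1 by -1.52 ± 0.17 and TOC1 by -0.11 ± 0.13, so time of day stays open for that comparison too. A delay of stem development under parasitization is a hypothesis that these data do not test.

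The 104 features with 6-digit IDs, which the report's comparisons leave out, gave, when tested, 31 lower and no higher calls at stage 2, 18 higher and no lower calls between the control stages, and none at stage 1. Their median log2 change was -0.16 at stage 2 and 0.15 at stage 1.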
